A study of Lactobacillus delbrueckii subsp. bulgaricus 2038 with 12 samples.

How the data were processed

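Total RNA of Lactobacillus delbrueckii subsp. bulgaricus 2038 was measured in 12 samples, 3 in each of 4 groups (start control, 2, 7 and 9 h), on arrays hybridised with a single Cy3-labelled sample each. Per the labels' protocols, glycerol stock was inoculated into 8 ml of medium at 40 °C with shaking at 10 rpm, RNA was isolated with acid phenol and treated with DNase, and the RNA was amplified linearly and labelled through aminoallyl-UTP. The submitters' processing notes name Agilent Feature Extraction 10.5. Per the file headers, the 4 arrays of replicate 1 were extracted with Feature Extraction version 10.5.1.1 and the 8 arrays of replicates 2 and 3 with 10.7.3.1. Each replicate number is 1 slide with its own scan day, and each of the 3 slides holds all 4 groups.

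The authors deposited the scanner output of each array as spot intensity on a linear scale, where the processed signal is the background-subtracted intensity, per the file headers. The authors also deposited a matrix of log2 values with 1869 rows, of which 60 are controls. Those log2 values equal the mean log2 processed signal of the unflagged spots of each probe within 0.0001 on all 12 arrays. Their direction and log base are thereby known, and the matrix carries no scaling between arrays. Its column medians were 10.72, 10.52 and 10.06 for the start control, 10.89, 10.69 and 10.46 at 2 h, 10.38, 10.09 and 9.77 at 7 h, and 10.18, 9.99 and 9.68 at 9 h, in replicate order.

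An array holds 1809 probes of 60 bases other than controls, each printed as 8 spots, which makes 14472 spots. Each probe has its own locus, with 1765 probes of LBU loci and 44 probes of identifiers that begin with stu. No table in the sources used here pairs these identifiers with gene names, and the description of every probe reads unknown. Spots flagged as non-uniform or as population outliers were left out, between 82 and 283 per array, and no spot was saturated. Log2 of the processed signal was averaged over the spots of a probe, and the log2 of the array's 75th percentile over unflagged spots other than controls was subtracted. A locus counted as above background on an array where at least 0.5 of its spots were well above background, and it was tested if this held on at least 2 of the 3 arrays of a group. This left 1763 loci (1761 LBU and 2 stu) and removed 4 LBU and 42 stu loci, while 1706 loci were above background on all 12 arrays.

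Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit on the means of all 4 groups and eBayes, so that the comparisons share 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05, and counts are also given with a limit of 2-fold. The median SD of a locus across replicates was 0.09 in the start control, 0.08 at 2 h, 0.08 at 7 h and 0.07 at 9 h on the log2 scale. The fit was tested on simulated data for 7 h against the start control, with 200 of 1763 loci changed: it recovered 56% of changes of 0.25, 90% of those of 0.5 and 100% of those of 1 and 2 (log2), with 8 false calls among 1563 unchanged loci. The real comparison called 1492 loci (84.6%). The adjustment depends on the share of changed loci, so recovery of small changes may differ in the real data.

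The rule for loci named in the text, fixed before the data were examined, took the largest rises and falls past the threshold whose groups of arrays do not overlap. Its condition on gene names could not be applied, and the number was reduced to 2 rises and 2 falls per comparison among LBU loci. Its parts for fixed gene lists and for genes fixed by name, and the tests of 20 gene lists by pathway, were not run because the lists are written in gene names. Runs of consecutive tags were chosen after the data had been seen, and the 2 longest per direction are described. Among runs of equal length, those with the larger median change were taken. Also described are the rising runs from 2 to 7 h whose median had fallen at least 2-fold by 2 h. A run is at least 5 consecutive numbers among 1760 LBU loci with a 4-digit tag, all past the threshold and 2-fold in 1 direction, and tag order stands in for no map of the genome. As a check of the code alone, the search found 19 of 19 runs planted among shuffled calls of 7 h against the start control. The definition of a run fixes this outcome. It also found 2 other runs, and 2 were present before planting. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps, and matplotlib 3.10.9 for the plots.

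Replicate numbers came from the labels. Deviations from the group means correlated between arrays of the same number in all 18 pairs (r from 0.62 to 0.91), and 12 of 12 arrays correlated best with their own number, so the numbers pair the arrays by slide. The SD of the log2 difference between arrays of a group was 0.17 to 0.24 with replicate 1 and 0.07 to 0.12 between replicates 2 and 3. Each array was counted as a replicate, as the labels number them. Within each slide, every locus called at least 2-fold moved in the called direction (100% in each comparison), and between 83.3% and 100% of these reached 2-fold within the slide. The loci were called from these same slides, so this agreement follows from the selection and gives no separate support. Folds of slides 2 and 3 correlated with those of slide 1 across loci with r between 0.95 and 1.00.

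Alternatives fixed before the data were examined were the replicate number as a block, quantile normalization, median centring, the deposited matrix, no filter, a filter on all 12 arrays, eBayes with trend and robust options, a fit on the groups compared alone, the 2-fold limit, and leaving out each array and each slide. Background correction by normexp with offset 50 was planned on the mean signal, which 8 arrays lack, and was run on the median signal followed by quantile normalization. The offset is added to every signal, which shrinks the folds of dim loci by construction.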

Results

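Total RNA of Lactobacillus delbrueckii subsp. bulgaricus 2038, a lactic acid bacterium used as a yogurt starter, was measured on 12 single-colour Agilent arrays. The arrays fall into 4 groups of 3 replicates. The start control was collected after 20 min in fresh whey medium at 40 °C, and the other groups were collected 2, 7 and 9 h after inoculation into a medium that the labels describe as conditioned with casein proteins. The title of the series names gene expression behind the formation of amino acids as its subject. Because the start control grew in a different medium, a difference from it covers both the medium and the time. Among 2, 7 and 9 h the medium is shared, and the labels name time as the difference. If the replicates of a time came from a single culture, such a difference covers the culture as well. Between 94.9% and 97.3% of the spots of an array were well above background, and the 75th percentile of the processed signal lay between 2808 and 5846 across arrays. The number of arrays limits the precision of each value. The files identify genes by locus tags (LBU and a number) without pairing them with gene names, so loci are given by tag, at most 2 that rose and 2 that fell in a comparison. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical.

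Of the 1763 loci tested, 1668 (94.6%) differed among the 4 groups by limma's moderated F-test with Benjamini-Hochberg adjustment. At least 1 of the 5 pairwise differences reached 2-fold in 872 of these.

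At 2 h after inoculation, the locus LBU0397 stood 53.7-fold below the start control and its neighbour by number, LBU0398, 48.9-fold, the largest falls of this comparison. The comparison covers the medium as well as the time. LBU1440 rose 11.8-fold and LBU1439 rose 9.31-fold. The normalised log2 signal of LBU0397, read by the probe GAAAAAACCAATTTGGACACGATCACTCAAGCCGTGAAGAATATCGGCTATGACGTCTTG, went from 2.23 ± 0.07 in the start control to -3.52 ± 0.04 at 2 h (SD, n = 3 each). LBU0398, with the probe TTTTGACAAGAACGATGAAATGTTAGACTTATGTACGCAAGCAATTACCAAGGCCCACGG, went from 1.14 ± 0.20 to -4.48 ± 0.13 (SD, n = 3). LBU1440, with the probe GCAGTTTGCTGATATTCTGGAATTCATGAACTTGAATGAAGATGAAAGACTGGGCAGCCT, went from -2.92 ± 0.27 to 0.64 ± 0.14 (SD, n = 3). LBU1439, with the probe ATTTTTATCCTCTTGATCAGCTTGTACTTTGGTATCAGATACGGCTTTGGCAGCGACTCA, went from -1.73 ± 0.03 to 1.49 ± 0.02 (SD, n = 3). The limma adjusted p was 1.71e-14 for LBU0397, 2.11e-11 for LBU0398, 6.48e-10 for LBU1440 and 2.44e-13 for LBU1439. In all 4 loci the 3 arrays at 2 h lay on 1 side of the 3 arrays of the start control, as the rule for named loci requires.

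Across all loci, 1366 differed between 2 h and the start control by limma at the adjusted threshold of 0.05, of which 659 rose and 707 fell. At least 2-fold changes numbered 294, with 174 rising and 120 falling, and at least 4-fold changes were 22 rises and 30 falls. The groups of arrays did not overlap for 77.8% of loci, where chance gives 10%. On the deposited matrix values, which are not scaled between arrays, 703 loci passed the threshold, 508 rising and 195 falling.

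Loci with adjacent tag numbers changed together at 2 h. The 12 loci from LBU0761 to LBU0772 all rose at least 2-fold, with a median log2 change of 1.76, and the 9 loci from LBU1232 to LBU1240 all rose with a median of 1.63. The 7 loci from LBU0163 to LBU0169 all fell, with a median of -2.77, and so did the 7 loci from LBU0197 to LBU0203, with a median of -1.62. Looking for such runs, of at least 5 consecutive tags called 2-fold in 1 direction, was decided after the data had been seen. There were 9 runs holding 66 of the called loci, and shuffling the calls over the tags gave 0.019 runs on average (1000 shuffles, permutation p = 0.001, the smallest they can give). The highest limma adjusted p in the 4 named runs was 1.24e-05.

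By 7 h the largest rises were those of LBU1254, 90.5-fold above the start control, and LBU1253, 87.6-fold. LBU0397 and LBU0398 stayed low, 53.1-fold and 46.8-fold below the start control. LBU1254, read by the probe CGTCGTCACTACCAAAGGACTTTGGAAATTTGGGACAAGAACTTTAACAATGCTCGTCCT, went from -4.43 ± 0.10 to 2.07 ± 0.10 (SD, n = 3). LBU1253, with the probe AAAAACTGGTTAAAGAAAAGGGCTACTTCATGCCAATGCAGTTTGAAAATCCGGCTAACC, went from -0.81 ± 0.25 to 5.64 ± 0.12 (SD, n = 3). With normexp background correction, whose offset of 50 shrinks the folds of dim loci by construction, the log2 change of LBU0398 was -4.80, against -5.55. The limma adjusted p was 7.65e-14 for LBU1254, 3.74e-12 for LBU1253, 1.33e-14 for LBU0397 and 7.39e-12 for LBU0398.

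**Figure D1:**
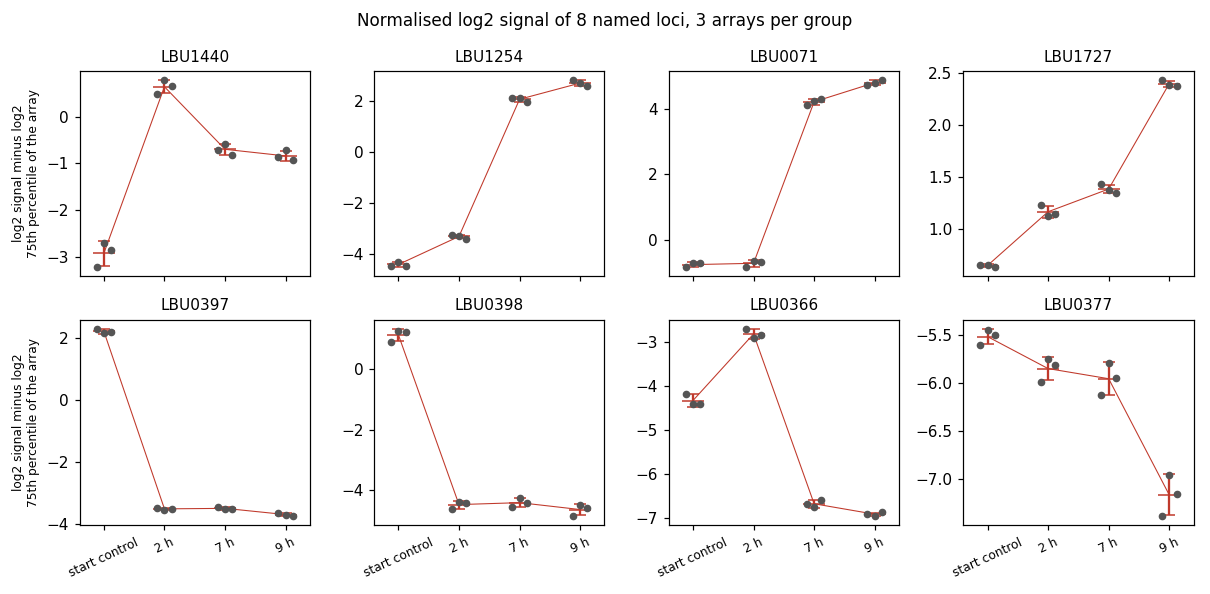
Normalised log2 signal (y axis, log2 signal minus the log2 75th percentile of the array, with a separate range in each panel) of 8 loci in the start control and at 2, 7 and 9 h (x axis). Grey points are the 3 arrays of a group, red bars the mean and SD, and red lines join the means. LBU1254 stood at -4.43 in the start control and 2.71 at 9 h, while LBU0397 went from 2.23 to -3.70.

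In the comparison of 7 h with the start control, 1492 loci differed by limma, 582 rising and 910 falling, and 640 did so at least 2-fold, of which 216 rose and 424 fell. The median change over all loci was -0.25 on the log2 scale under the scaling used, against -0.06 after quantile normalization, where 278 loci rose and 322 fell at least 2-fold. Changes near the median are therefore relative to that shift, while those of the named loci were many times larger. Median centring gave a median of -0.08. Normexp gave 223 rises and 253 falls of at least 2-fold, and on the deposited unscaled values 293 loci rose and 831 fell past the threshold.

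The longest run of this comparison held 31 loci, LBU0316 to LBU0346, all of which fell at least 2-fold with a median of -1.49. These were bright loci: the median of their normalised log2 signal was 4.62 ± 0.06 in the start control, 3.92 ± 0.04 at 2 h and 3.14 ± 0.02 at 7 h (SD, n = 3). The 13 loci from LBU0394 to LBU0406, which include LBU0397 and LBU0398, fell with a median of -3.79. The 15 loci from LBU1229 to LBU1243 rose with a median of 3.59, and the 12 from LBU0761 to LBU0772 rose with a median of 2.98. Altogether 29 runs held 220 of the 640 loci, 8 of them rising and 21 falling, against 1.07 runs on average after shuffling (permutation p = 0.001, the smallest that 1000 shuffles can give). The highest limma adjusted p in the 4 named runs was 6.23e-07. With normexp background correction and quantile normalization, an alternative chosen after the data had been seen, 19 runs were found, 9 rising and 10 falling, and 21 of the 31 loci from LBU0316 to LBU0346 were called 2-fold (23 of 31 at 9 h).

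**Figure D2:**
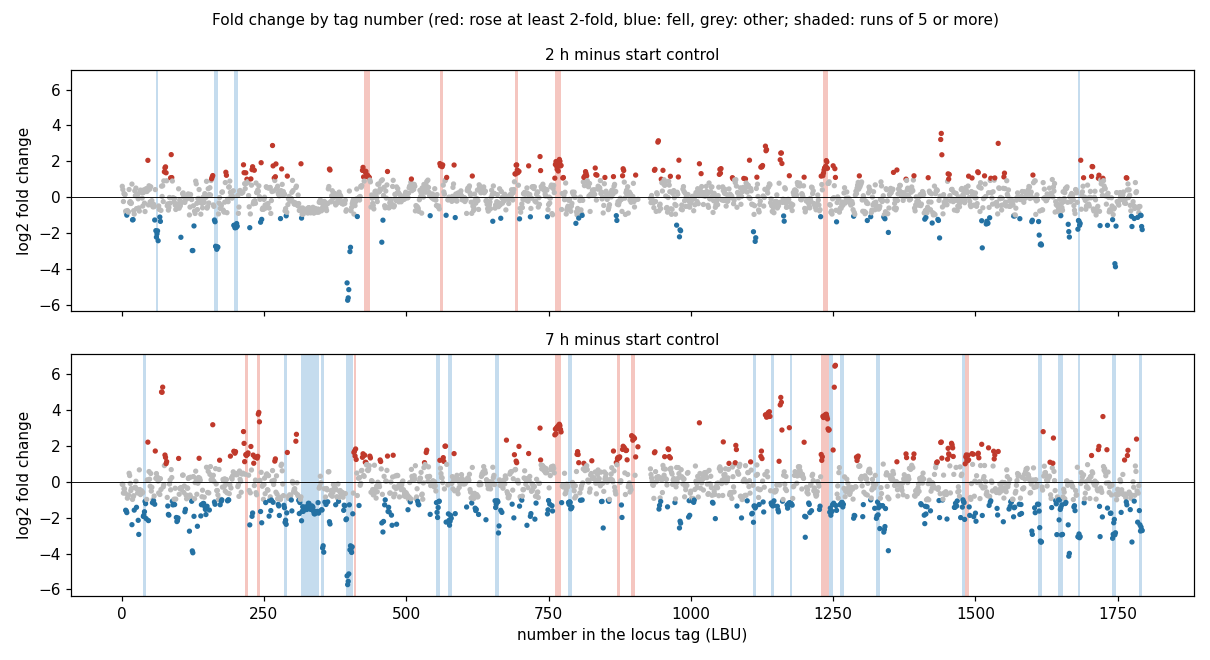
Log2 fold change against the start control (y axis) by the number in the locus tag (x axis), at 2 h (top) and 7 h (bottom), 1 point per locus. Red points rose and blue points fell at least 2-fold by limma at an adjusted p under 0.05, grey points did neither, and shaded bands are runs of at least 5 consecutive tags. The broad blue band at 7 h is the 31 loci from LBU0316 to LBU0346.

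At 9 h the same 4 loci led the comparison with the start control. LBU1254 stood 141-fold and LBU1253 105-fold above it, and LBU0397 stood 61.0-fold and LBU0398 54.8-fold below it. With normexp background correction, the log2 change was 6.44 for LBU1254, against 7.14, and -4.91 for LBU0398, against -5.78. The limma adjusted p values of the 4 loci, in the order named, were 3.77e-14, 2.40e-12, 1.23e-14 and 4.62e-12. In all, 1494 loci differed, 600 rising and 894 falling, and 673 differed at least 2-fold, 247 rising and 426 falling. Quantile normalization gave 297 rises and 324 falls of at least 2-fold, and normexp 233 and 256. On the deposited unscaled values 277 loci rose and 930 fell past the threshold. The 31 loci from LBU0316 to LBU0346 fell with a median of 3.04-fold and the 13 from LBU0394 to LBU0406 with a median of 16.7-fold, while the 12 from LBU0761 to LBU0772 rose with a median of 6.01-fold and the 12 from LBU1232 to LBU1243 with a median of 8.55-fold.

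Of the 2-fold calls against the start control, 89 loci rose and 71 fell at all 3 times. Between 2 and 7 h, 93 rises and 75 falls were shared, where independent lists of the same sizes would share 21.3 and 28.9. Between 7 and 9 h, 197 rises and 388 falls were shared, where independent lists would share 30.3 and 102. Across loci, which are not independent replicates, the log2 changes at 2 h correlated with those at 7 h with r = 0.62 and a covariance of 0.673, and those at 7 and 9 h with r = 0.98 and a covariance of 1.66. In groups simulated without change and compared with a shared simulated control, r was 0.50 and the covariance 0.0043. Calls shared in the same direction at the threshold alone averaged at most 0.01 there. Their real counterparts were 986 for 2 and 7 h and 1361 for 7 and 9 h. Without any change so few calls are fixed in advance, so the simulated count says nothing about the overlap. The simulated covariance of 0.0043 is far below 0.673 and 1.66. This argues against the spread between the shared control arrays as the main source of the real covariance. A deviation common to the 3 control arrays, which the simulation leaves out, may still make up the excess. The different medium of the start control would be such a deviation, shared by all 3 times. This was not tested, since these controls could not be split into parts of at least 2.

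The step from 2 to 7 h, in the same medium, brought the largest rises in LBU1254 (42.1-fold) and LBU0071 (31.0-fold) and the largest falls in LBU0366 (14.6-fold) and LBU0365 (13.9-fold). LBU0071, read by the probe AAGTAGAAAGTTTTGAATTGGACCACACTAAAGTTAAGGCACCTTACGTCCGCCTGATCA, stood at -0.77 ± 0.07 in the start control, -0.73 ± 0.10 at 2 h and 4.23 ± 0.09 at 7 h (SD, n = 3). LBU0366, with the probe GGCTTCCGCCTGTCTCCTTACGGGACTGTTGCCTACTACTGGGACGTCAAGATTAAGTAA, went from -4.33 ± 0.14 in the start control to -2.81 ± 0.10 at 2 h and -6.68 ± 0.08 at 7 h (SD, n = 3). LBU0365, with the probe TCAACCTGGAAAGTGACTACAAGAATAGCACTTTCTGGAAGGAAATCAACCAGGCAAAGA, went from -4.19 ± 0.07 at 2 h to -7.98 ± 0.30 at 7 h (SD, n = 3), where it was well above background on 2 of the 3 arrays. With normexp background correction and its offset, LBU0366 fell by 2.17 and LBU0365 by 1.58 on the log2 scale. The offset shrinks the folds of such dim loci by construction. The limma adjusted p was 5.24e-13 for LBU1254, 5.09e-13 for LBU0071, 5.68e-12 for LBU0366 and 2.33e-08 for LBU0365.

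In this step 1404 loci differed, 474 rising and 930 falling, and 445 did so at least 2-fold, 151 rising and 294 falling. Quantile normalization gave 193 rises and 210 falls, normexp 149 and 153, and the deposited unscaled values 100 and 617, of at least 2-fold. Past the threshold alone, the deposited values gave 155 rises and 1034 falls. The 12 loci from LBU1232 to LBU1243 rose with a median of 2.06, and the 9 from LBU0764 to LBU0772 with a median of 1.25, of which 2 of 9 were called 2-fold on the deposited values. The 6 loci from LBU0574 to LBU0579 fell with a median of -2.04, and the 6 from LBU1680 to LBU1685 with a median of -1.58. Of the loci from LBU0574 to LBU0579, 0 of 6 were called 2-fold under normexp. These loci were dim, with a median signal of -6.21 at 7 h, and the offset of normexp shrinks such folds by construction. The 7 loci from LBU0197 to LBU0203, which had fallen by 2 h, rose with a median of 3.26 to a median signal of 0.02 ± 0.20 at 7 h, against -1.74 ± 0.29 in the start control (SD, n = 3), and 4 of the 7 were called at least 2-fold above the start control at 7 h. Other runs came back closer to the start control. The 5 loci from LBU0165 to LBU0169 rose with a median of 2.42, and their median change against the start control at 7 h was -0.48. For the 6 loci from LBU0059 to LBU0064 these medians were 2.22 and 0.26. Among 2-fold calls, 44 loci rose by 2 h and fell by 7 h, and 31 fell by 2 h and rose by 7 h, while 32 rose in both steps and 25 fell in both. These steps share the 2 h arrays, and the first covers the change of medium as well. Independent lists would give 29.0, 10.3, 14.9 and 20.0. Simulated unchanged groups gave 0 loci with opposite steps, which their lack of change fixes in advance, so this count says nothing about reversals.

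From 7 to 9 h few loci moved far. LBU1417 rose 2.25-fold and LBU1727 rose 2.02-fold, while LBU0378 fell 2.46-fold and LBU0377 fell 2.30-fold. LBU1417, read by the probe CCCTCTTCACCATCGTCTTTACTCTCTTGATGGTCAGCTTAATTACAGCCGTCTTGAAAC, went from -4.55 ± 0.11 to -3.38 ± 0.08, and LBU1727, with the probe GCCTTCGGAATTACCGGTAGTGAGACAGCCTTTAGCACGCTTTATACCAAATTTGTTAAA, from 1.38 ± 0.04 to 2.40 ± 0.03 (SD, n = 3). LBU0378, with the probe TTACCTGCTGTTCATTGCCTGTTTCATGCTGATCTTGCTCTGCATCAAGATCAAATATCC, went from -7.18 ± 0.23 to -8.48 ± 0.20 (SD, n = 3) and was well above background on 2 of the 3 arrays at 9 h. LBU0377, with the probe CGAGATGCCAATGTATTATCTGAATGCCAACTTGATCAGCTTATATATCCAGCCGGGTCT, went from -5.96 ± 0.17 to -7.16 ± 0.21 (SD, n = 3). The limma adjusted p was 1.62e-06, 9.50e-08, 2.44e-05 and 1.85e-05 in the order of LBU1417, LBU1727, LBU0378 and LBU0377.

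The SD of the log2 changes across loci was 0.29 in this step, against 1.00 between 2 and 7 h. Limma called 757 loci, 391 rising and 366 falling, but 12 at least 2-fold, 2 rising and 10 falling, and 69.9% of loci stayed within 1.2-fold. With the replicate number as a block 1292 loci were called, without replicate 2 of every group 368, without replicate 3 403, and on the deposited unscaled values 44. Median centring gave 257 rises and 492 falls. At least 2-fold, quantile normalization gave 5 rises and 7 falls, of which 5 calls were among the 12, and the deposited values 1 rise and 16 falls. With normexp background correction on the median signal, 2 loci rose and 0 fell at least 2-fold, and 0 of these were among the 12: LBU1417 rose by 0.81 and LBU1727 by 0.84 on the log2 scale, while LBU0378 and LBU0377, both dim, fell by 0.33 and 0.48. The offset of normexp shrinks the folds of dim loci by construction, so their smaller falls cannot be laid to the background correction. LBU1727 also stayed under 2-fold after quantile normalization (0.85) and median centring (0.95) and on the deposited values (0.85), and without replicate 3 at 7 h or replicate 1 at 9 h, where 1 locus rose at least 2-fold. No run of 5 consecutive tags was found, but with 12 calls shuffling gave 0 runs too, so this says nothing about neighbours. The log2 changes of adjacent tags correlated in this step with r = 0.535 across 1748 pairs. The highest of 1000 shuffles was 0.07.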

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

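The tests of the stu probes below were chosen after the result had been seen. Probes whose identifiers begin with stu lie outside the comparisons, apart from 2 that passed the filter. On replicate 2 at 9 h, 110 of their 352 spots were well above background, against 10 to 33 on the other 11 arrays, and their median signal was 7.56 against 2.27 to 3.42. A raised background over the whole array is argued against, since the median of the negative controls there was 0.8697 times the higher of the other 2 arrays at 9 h. Non-specific binding that would also reach the control probes is argued against too, since the highest ratio among 4 families of control probes was 1.06, while that of the stu probes was 2.66. These control probes cannot show binding particular to the stu sequences, which stays open. Labelled RNA that matches these probes on this array alone stays open: 19 of the 44 probes were at least 2-fold brighter than on both other arrays at 9 h, which restates the brighter signal and decides nothing. The median stu signal was 0.641% of the median LBU signal on that array.

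Past the limma threshold at both times, 7 loci lay at least 2-fold below the start control at 2 h and at least 2-fold above it at 7 h, and 8 lay above it at 2 h and below it at 7 h, where independent lists would give 14.7 and 41.8. The 2 comparisons share their control arrays and correlate across loci (r = 0.62), so they are not independent. Fewer opposite calls than in independent lists therefore say nothing further. As these loci were picked for lying on opposite sides of the start control, a difference between 2 and 7 h follows from the choice and was not tested apart from it.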

How the results depend on the processing

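The normexp alternative and all values for runs of tags were chosen after the data had been seen, and the other alternatives before. All 20 values of named loci kept their direction and stayed past the threshold under the alternatives that gave them a value. LBU0365 and LBU0378 have none under the filter on all 12 arrays, which removes them. The 2-fold limit left 294, 640, 673, 445 and 12 loci in the 5 comparisons in their order above, and 872 of those differing at any time, by its own construction. On the deposited values, which carry no scaling between arrays, 703 loci were called at 2 h against the start control, 717 at least 2-fold from 2 to 7 h and 44 from 7 to 9 h. The replicate number as a block raised the calls from 7 to 9 h from 757 to 1292. It changed no call of a named locus and no count of 2-fold calls, and gave 1570, 1646, 1639 and 1598 calls in the other 4 comparisons, each within 1.5 times. Leaving out arrays or slides gave 368 to 1062 calls from 7 to 9 h, the lowest without replicate 2, and 403 without replicate 3. The other totals stayed within 1.5 times, but the 2 rises of 2-fold from 7 to 9 h became 1 without replicate 3 at 7 h and without replicate 1 at 9 h. Normexp called 2 loci 2-fold from 7 to 9 h, both rising, and 0 of them were among the 12. The split of 2-fold calls into rises and falls depended on the scaling: quantile normalization gave 278 and 322 against 216 and 424 at 7 h, 297 and 324 against 247 and 426 at 9 h, and 193 and 210 against 151 and 294 from 2 to 7 h, where median centring gave 184 and 222. Normexp, which changes background and scaling together and adds an offset of 50, gave 223 and 253, 233 and 256, and 149 and 153. The offset shrinks the folds of dim loci by construction, so calls lost under normexp cannot be laid to background or scaling alone. Among all calls from 2 to 7 h (474 and 930), quantile normalization gave 660 and 748, median centring 647 and 761, and normexp 642 and 735. From 7 to 9 h quantile normalization gave 5 rises and 7 falls of 2-fold against 2 and 10, and 5 of its 12 calls were among the 12. The deposited values gave 241 and 86 of 2-fold at 2 h and 165 and 621 at 9 h, 293 and 831 of all calls at 7 h, 277 and 930 at 9 h, 155 and 1034 from 2 to 7 h and 3 and 41 from 7 to 9 h, and 1 and 16 of 2-fold from 7 to 9 h. Runs of tags numbered 19 at 7 h under normexp against 29, and 41 from 2 to 7 h on the deposited values against 16. The cause of these shifts was not tested. The means and the brightest of several probes per locus were not run, since each locus has 1 probe, and the gene list tests and normexp on the mean signal were not run. Signal over background limits the dimmest loci, as for LBU0378 and LBU0365.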

Other observations

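The search for runs of tags and the tests of neighbouring tags and of falls against rises were chosen after those patterns had been seen, and the splits within slides after the other splits, each test before its own result, except that the range within slides for signal close to background was added after its ratio had been seen. Further runs of consecutive tags differed between 7 h and the start control. The 6 loci from LBU1244 to LBU1249 fell with a median of -1.65 directly after the rising run that ends at LBU1243. The 5 loci from LBU0238 to LBU0242 rose with a median of 3.35. The median of their normalised log2 signal was -1.40 ± 0.09 in the start control, -1.33 ± 0.19 at 2 h and 1.98 ± 0.13 at 7 h (SD, n = 3). In addition, the 5 loci from LBU1680 to LBU1684 fell with a median of -3.06, having fallen with a median of -1.46 by 2 h.

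The log2 changes of adjacent tags at 7 h correlated across 1748 pairs with r = 0.61, and 10 tags apart with r = 0.06, where the highest of 1000 shuffles was 0.08 for adjacent tags. GC content of the probes is argued against as the cause, since the correlation was 0.5997 after a quadratic fit on GC. Printing neighbours close together is argued against, since the distance between the spots of adjacent tags was 0.9559 times that of random pairs, and shared probe sequence is argued against, since r was 0.6164 without the loci that share 20 bases with another probe. Joint transcription of neighbouring genes may underlie the runs, as a hypothesis that was not tested, because no genome or map of genes was used here.

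More loci fell than rose at least 2-fold at 7 h against the start control, 424 against 216. A fit on GC cannot decide on GC content, since it keeps the median change and so holds this balance nearly fixed. The ratio of falls to rises, 1.96, was 1.949 after it. Across 1763 loci, however, the log2 changes at 7 h correlated only weakly with probe GC (r = -0.07, Spearman -0.05). This argues against GC content as the main source of the excess of falls. Signal close to background is argued against as the whole cause under this scaling, since the ratio was 1.298 among the loci above the median of mean signal (170 falls and 131 rises), with 1.21 to 1.34 within slides. This is below the 1.96 over all loci, so the excess of falls was stronger among the dimmer loci. A part played by dim signal therefore stays open. Normexp gave 253 falls and 223 rises, but it changes the background and, through quantile normalization, the scaling together. Its offset also shrinks the folds of dim loci by construction. The scaling stays open too and cannot be told apart from a real excess of falls, since the lower ratio under median centring and quantile normalization was 1.158. That ratio came from quantile normalization, with 322 falls and 278 rises. Median centring gave 345 falls and 263 rises, and the deposited unscaled values 535 falls and 185 rises.

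A gene dosage effect, with more copies near a replication origin at tag 1, could lower the changes with distance from that tag at 2 h. The Spearman correlation was instead above 0, at 0.16 over 1760 loci, with a circular-shift permutation p of 0.06414 (0.160 adjusted over 5 comparisons), so the predicted direction was not seen. The origin at tag 1 and a circular tag order were assumed, since no map of the genome was used. Over the comparisons the correlation ranged from -0.18 from 7 to 9 h to 0.19 at 7 h against the start control. The circular-shift permutation p of the latter was 0.04629 (0.160 adjusted). A difference of loci whose probe encodes a hydrophobic segment could not be tested: 51.6% of loci have a single readable frame, below the 80% needed, and 14 were hydrophobic. For 7 h against 2 h the permutation p by circular shift was 0.7577, and 0.676 of the difference was left after the fit on GC.

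Of the 10 ways to split the 6 arrays of each comparison into 3 and 3, 1 gave as many loci as the real one, which is the real split. With 10 splits a share under 0.05 is out of reach. The counts were 1366, 1492, 1494, 1404 and 757 in the real splits, and the highest in another split was 0 in the first 4 comparisons and 1 from 7 to 9 h. For differences at any time, 1 of 100 splits of the 12 arrays, the real one, gave 1668 loci, and the highest other gave 806. Since the arrays pair by slide, 100 splits that keep 1 array of each slide in each group were also drawn. Of these 1, the real one, gave 1668 loci, and the highest other gave 1571; with the replicate number as a block 1 gave 1749 and the highest other 1625. The highest other split exchanges the arrays of replicate 2 at 7 and 9 h alone and so keeps most of the real grouping. Among the splits drawn, only the real one reached its count, which argues against chance in the assignment of arrays within slides for the count at any time. The splits cannot speak to chance differences between cultures, since the replicates may be technical.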
